A study of Danio rerio with 14 samples.

How the data were processed

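The series measured where Rad21, a subunit of the cohesin complex that holds sister chromatids together and shapes chromatin loops, binds the genome of whole zebrafish embryos (Danio rerio, strain AB/PS) around the time at which the embryo's own genome is switched on. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with an antibody against Rad21 at 2.5, 4.5 and 10 hours post fertilisation (hpf) and with an antibody against CTCF, a DNA-binding zinc finger protein at which cohesin is known to halt, at 10 hpf. The 14 samples fall into 7 groups of 2, the immunoprecipitated samples and an input control without antibody for each stage. Per the labels' protocols, the members of a group came from independent collections of embryos, with 2000 embryos pooled at 2.5 hpf and 1000 at the later stages, and chromatin was sheared in 6 cycles at 2.5 hpf and in 10 cycles later. The 2.5 hpf libraries were made with another kit, at another site and as 125 bp paired-end reads, against 50 bp single-end reads for the later stages, so that stage and library preparation cannot be separated at 2.5 hpf.

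Alignment with Bowtie2 2.2.1 to the Zv9 build and use of HOMER are named in the submitters' processing notes. The deposited files are 4 peak lists, one for each stage and antibody. Per the file headers, both Rad21 libraries and both inputs were pooled for the 2.5 hpf list. A single tag directory per stage and antibody, with a single input directory, entered each of the others. This was taken as a pool of both libraries, a reading the headers do not state. No value is given per library, so no spread between replicates could be computed, and the depth of a single library is not given in the sources used here. The labels' protocols state 20000000 to 50000000 reads per library at 2.5 hpf and 20000000 later.

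The lists were made with different peak callers. At 2.5 hpf peaks were called with MACS2 2.1.0.20151222 at a q-value of 0.05 from both Rad21 libraries against both inputs, per the file headers, with 1 tag kept per position. The header gives 15362000 tags for the immunoprecipitated libraries, of which 5245276 were left after duplicates were removed (a redundant rate of 0.66), and 21987080 for the inputs, of which 19827134 were left (a redundant rate of 0.10). The other 3 lists were called with HOMER at a false discovery rate of 0.001, with 4-fold enrichment required over input and over the surrounding 10000 bp, per the file headers. The headers give 14255160 tags for Rad21 at 4.5 hpf, 13260105 for Rad21 at 10 hpf and 28291282 for CTCF at 10 hpf, totals before the limit of tags per position. Multiplying the tags per bp in these headers by the genome size they give leaves 11780000, 11800000 and 27840000 tags, which were taken as the tags after that limit, a reading the headers do not state. Approximate immunoprecipitation efficiencies, the share of tags in peaks, were 1.03%, 3.38% and 1.03% in the same order, per the file headers. At most 1 tag per position was considered in the HOMER Rad21 lists and at most 2 in the CTCF list, and HOMER kept peaks of a list at least 336, 378 and 328 bp apart. The stricter and looser rules change how many peaks a list holds, so counts of peaks are compared between stages without a test.

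In the HOMER lists the deposited score is the same in every row and ranks nothing, and all peaks of a list have one width. The identifiers of these peaks carry a rank within the chromosome, which followed the order of the file closely (median Spearman rho across chromosomes of 0.85, 0.97 and 0.94 for Rad21 at 4.5 hpf, Rad21 at 10 hpf and CTCF, over peaks, which are not replicates). The order in which the peaks were deposited was therefore used as a rank in place of a score, a choice made after the files were seen, and what the order was sorted by is not given in the sources used here. The 2.5 hpf list gives for each peak the pileup (a signal, the coverage by tags at the summit), the fold enrichment (a ratio over the modelled local background) and −log10 of p and of q, all deposited by the authors and used only within that list. Its peaks were ranked by q. The background that MACS2 had modelled was recovered as (pileup + 1) / fold − 1 and divided by the genome average, the 5245276 tags times the fragment length of 209 bp over the genome size of 1450000000 bp in the header. The smallest value over all peaks was 1.000 times this average, the floor of such a model.

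Peaks on chromosomes 1 to 25 were used, which left out 1 peak, on the mitochondrial sequence at 2.5 hpf. Coordinates are 1-based on Zv9, and a chromosome's length was taken as the largest end over the 4 lists. Peaks of different lists counted as shared when they overlapped by at least 1 bp. Shared numbers were compared with 10000 circular shifts of the first list within each chromosome, as a one-sided permutation test with Benjamini-Hochberg adjustment over the 6 pairs of lists, for which 1e-04 is the smallest p the shifts can give. Shares carry exact (Clopper-Pearson) 95% confidence intervals, which cover counting error only. Differences of shares carry a percentile 95% interval from 10000 bootstrap draws of 1 Mb windows, because neighbouring peaks are not independent, and a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 3 pairs. Chromosomes were compared between lists by 150 two-sided Fisher's exact tests, adjusted together. Clustering was measured as the share of peaks with another peak of the list within 10 kb, against 1000 draws of uniform positions (smallest p 1e-03). Places in the deposited order were compared by two-sided permutation tests on the difference of medians with 100000 resamples (smallest p 1e-05). These p-values are over peaks of a single list per stage and antibody and say nothing of the spread between embryo collections.

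Regions were named by a rule fixed before the data were examined: for each list the 10 highest peaks by score, the 5 widest peaks and the 5 densest 1 Mb windows, for pairs of lists the 5 windows with the largest change in their share of peaks, and the 10 highest 10 hpf Rad21 peaks in each of the classes defined by overlap. Where the rule asks for a score, place in the deposited order stands in for it in the HOMER lists, since width, which the rule names as the substitute, is constant there. Comparisons by place in the list, the position along chromosomes and the split of chromosome 4 at 24 Mb were chosen after the data were seen. The planned comparisons with gene positions, gene lists and sequence motifs were not run, because the reference tables at hand are of another build than Zv9, so no gene is named.

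The overlap rules were tested on simulated data: 500 simulated peaks gave 0 disagreements with a direct search under the 3 overlap rules. With 2857 overlaps planted for 4.5 hpf Rad21 in 10 hpf Rad21, 2875 were found, of which 34.3 are the mean of the shifts, and of 100 unrelated pairs of lists of the same sizes 5 had p under 0.05. For 2.5 hpf in 10 hpf Rad21, 20 were planted and 30 found, of which 13.3 are the mean of the shifts, and 6 of 100 unrelated pairs had p under 0.05. In 100 simulations of the share at CTCF peaks with a true difference of 7 percentage points between 10 and 4.5 hpf, the bootstrap interval held the true value in 93. Simulated peaks lay at uniform positions without the runs of the real lists, so these rates do not cover clustered peaks. Alternatives tried were other overlap rules, merged peaks, fixed widths, other ways of shifting, lists without chromosome 4, the first peaks of each list, filtered 2.5 hpf lists and, for chromosomes, the bootstrap over 1 Mb windows in place of Fisher's exact test. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.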

Results

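Binding of Rad21 was mapped in pooled whole zebrafish embryos at 2.5 hpf, before the main wave of zygotic transcription, at 4.5 hpf, after it, and at 10 hpf, when gastrulation ends, and binding of CTCF was mapped at 10 hpf. Each stage and antibody had 2 libraries, as did each stage's input. The authors pooled them before peaks were called at 2.5 hpf, and the later lists were taken as pooled too. Each value below is that of a single list per stage and antibody and has no spread between replicates. The headers give 15362000 tags in total at 2.5 hpf, 14255160 at 4.5 hpf, 13260105 at 10 hpf and 28291282 for CTCF. With tags at the same position limited, 5245276 were left at 2.5 hpf, and the tags per bp in the other headers correspond to 11780000, 11800000 and 27840000. All positions are on Zv9.

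The first question was how many sites carry Rad21 as development proceeds. The lists held 2012 Rad21 peaks at 2.5 hpf, 7144 at 4.5 hpf and 18075 at 10 hpf, and the CTCF list held 14079. From 4.5 to 10 hpf the number of Rad21 peaks was 2.53 times higher and the covered length 2.83 times higher, with 0.93 times the total tags and 1.001 times those left after the limit per position. The share of tags in peaks, which grows with the number of peaks called, was 1.03% at 4.5 hpf and 3.38% at 10 hpf, and the mean number of tags per peak was 20.5 and 24.8. Rad21 peaks covered 806 kb at 2.5 hpf, 1207 kb at 4.5 hpf and 3416 kb at 10 hpf. Their median width at 2.5 hpf was 310 bp (range 209 to 3326), while the later lists hold peaks of one width, 169 bp at 4.5 hpf and 189 bp at 10 hpf. Numbers at 2.5 hpf come from another peak caller and another kind of library than the later ones, and merging peaks within 1 kb left 1348 regions at 2.5 hpf against 7068 and 17738 at the later stages.

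Rad21 sites of 4.5 hpf were often Rad21 sites at 10 hpf as well. Of the 7144 peaks at 4.5 hpf, 2946 overlapped a 10 hpf peak, or 41.2% (exact 95% interval 40.1 to 42.4), where shifted peaks gave a mean of 34.3, an 86.0-fold excess (permutation p = 1e-04, the smallest the shifts can give, adjusted p = 2e-04). These sites made up 16.3% (15.8 to 16.8) of the 10 hpf list, so 15129 of the 10 hpf peaks had no counterpart at 4.5 hpf, and 4198 of the 4.5 hpf peaks had none at 10 hpf. Among the first 10 peaks of the 4.5 hpf list, 9 overlapped a 10 hpf peak, among them the peaks at chromosome 16, 29670633 to 29670801, chromosome 7, 27753127 to 27753295, chromosome 20, 28868489 to 28868657, chromosome 21, 41891124 to 41891292, and chromosome 4, 2133833 to 2134001. All 5 of these sites were also among the first 10 of the 10 hpf list, at places 1, 3, 4, 6 and 8, and none of them overlapped a CTCF peak. The exception, the first peak of the 4.5 hpf list, lay on the long arm of chromosome 4, at 56016345 to 56016513.

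Sharing between these stages fell steadily along the lists. In the first decile of the 4.5 hpf list 92.6% (90.4 to 94.4) of 715 peaks overlapped a 10 hpf peak, against 13.6% (11.2 to 16.3) in the last decile. In the other direction, 56.2% (53.9 to 58.5) of the first decile of the 10 hpf list lay at a 4.5 hpf peak and 2.55% (1.87 to 3.38) of the last. Peaks of the 10 hpf list that overlapped a 4.5 hpf peak had a median place of 3202 in that list, against 10168 for the rest (permutation p = 1e-05, two-sided, the smallest the resamples can give). High in the 10 hpf list, yet absent from both earlier lists and from the CTCF list, were peaks at chromosome 18, 21732109 to 21732297 (place 19), chromosome 2, 24889651 to 24889839 (place 85), and chromosome 17, 38076641 to 38076829 (place 124).

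**Figure D1:**
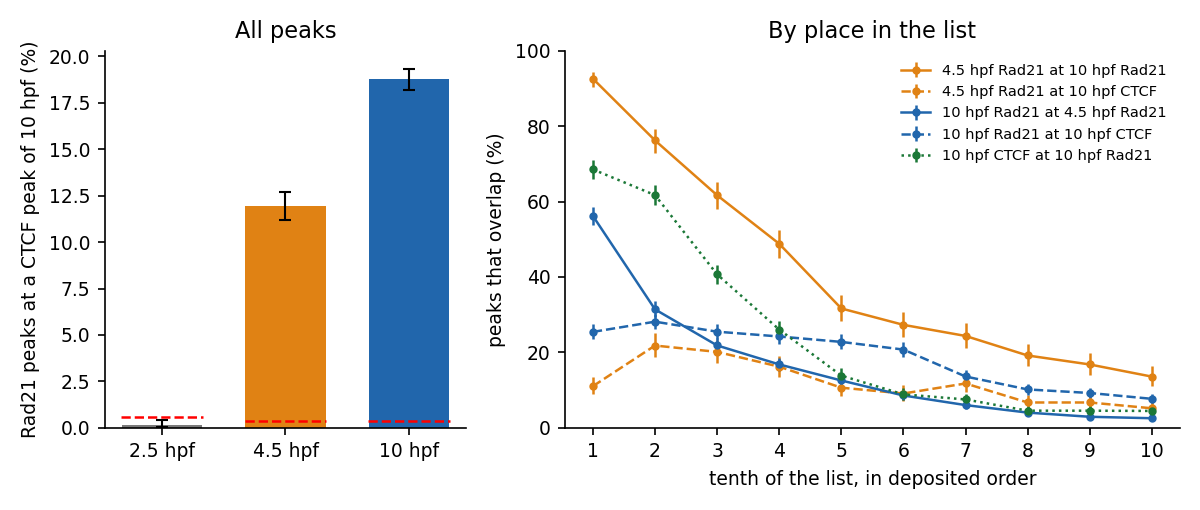
Left, share of each Rad21 list that overlaps a CTCF peak of 10 hpf (bars, in percent, with exact 95% intervals) and the mean share of shifted peaks (red dashed lines). Right, share of peaks that overlap another list (in percent, with exact 95% intervals) by decile of the list in deposited order; sharing between 4.5 and 10 hpf falls from 92.6% to 13.6% of the 4.5 hpf peaks, while the share of 4.5 hpf peaks at CTCF is 11.05% in the first decile and 21.8% in the second.

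Rad21 peaks of 2.5 hpf were nearly all at other places. Of 2011 peaks on the chromosomes, 2 overlapped a 4.5 hpf peak, or 0.10% (0.012 to 0.36), and 7 overlapped a 10 hpf peak, or 0.35% (0.14 to 0.72). Neither number exceeded that of shifted peaks, which averaged 5.78 and 15.1 (one-sided permutation p = 0.98 and 0.99, adjusted p = 1 for both). The shared peaks were at chromosome 18, 29352022 to 29354916 (fold enrichment 59.3), chromosome 11, 3922037 to 3923047 (fold 53.6), chromosome 16, 381176 to 381384 (fold 6.39), chromosome 13, 43124076 to 43124484 (fold 4.21), and 3 places near the end of chromosome 20, between 55775547 and 55790284 (fold 5.37, 4.55 and 6.53). The 2.5 hpf peaks on chromosomes 18 and 13 were those that overlapped a peak of both later Rad21 lists, though the later peaks need not overlap each other. The fold enrichments are the authors' values over modelled input. The peak with the highest enrichment at 2.5 hpf, chromosome 8, 5006471 to 5007368, with 144-fold enrichment and a pileup of 372 tags, overlapped no peak of the other lists. With the first 2011 peaks of each list, 4 of the 2.5 hpf peaks lay at 10 hpf peaks, 2.40 times the mean of the shifts, without passing the test (permutation p = 0.1).

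Many peaks at 2.5 hpf lay in dense runs. Another peak of the same list lay within 10 kb for 67.6% (window bootstrap 95% interval 60.8 to 73.0) of the 2.5 hpf peaks, 17.1% (15.7 to 18.4) of the 4.5 hpf peaks, 31.7% (30.6 to 32.7) of the 10 hpf peaks and 19.8% (18.9 to 20.7) of the CTCF peaks. Uniform positions gave 4.51%, 10.2%, 23.9% and 19.2% in the same order, so the excess was 15.0-fold at 2.5 hpf, 1.67-fold at 4.5 hpf and 1.32-fold at 10 hpf (permutation p = 1e-03 each, the smallest the draws can give), and CTCF peaks did not pass (1.03-fold, permutation p = 0.06). With only the 2.5 hpf peaks of at least 4-fold enrichment the share was 34.9% and the excess 14.2-fold, and with only those on a background under 2 times the average 12.6% and 15.3-fold (permutation p = 1e-03 each, the smallest the draws can give). The later lists were called with 4-fold enrichment over the surrounding 10000 bp and a minimum distance between peaks, which works against runs. The densest 1 Mb windows at 2.5 hpf were chromosome 8 from 35 Mb with 83 peaks, chromosome 24 from 12 Mb with 77, chromosome 12 from 16 Mb with 53, chromosome 20 from 55 Mb with 51 and chromosome 16 from 20 Mb with 49. These windows held 15.6% of the list, and in the same order 1, 1, 7, 1 and 5 peaks at 4.5 hpf and 5, 7, 8, 9 and 7 at 10 hpf. They were also the windows whose share of peaks changed most between 2.5 and 4.5 hpf, which follows from their density, since no window at 4.5 hpf held more than 19 peaks. The densest windows of the later Rad21 lists were chromosome 14 from 31 Mb at 4.5 hpf, with 19 peaks, and chromosome 13 from 30 Mb at 10 hpf, with 41.

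Sequence in these runs had a high background in the input model. The median modelled background was 28.3 times the genome average for the 1359 peaks with a neighbour within 10 kb and 1.46 times for the 652 without one, a 19.4-fold ratio (permutation p = 1e-05, two-sided, the smallest the resamples can give). That test takes peaks as independent, which peaks of one run are not, and windows were not resampled here. Median fold enrichment was 3.37 for peaks with a neighbour and 4.99 for those without. This contrast follows in part from the listing, since on a low background a peak passes the q threshold only at a higher fold. The background was also recovered from the fold itself. In the densest window, on chromosome 8, the median background was 8.75 times the average and the median fold enrichment 3.39. The widest peak, chromosome 7, 64247970 to 64251295, stood at 3.38-fold enrichment on a background of 132 times the average.

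**Figure D2:**
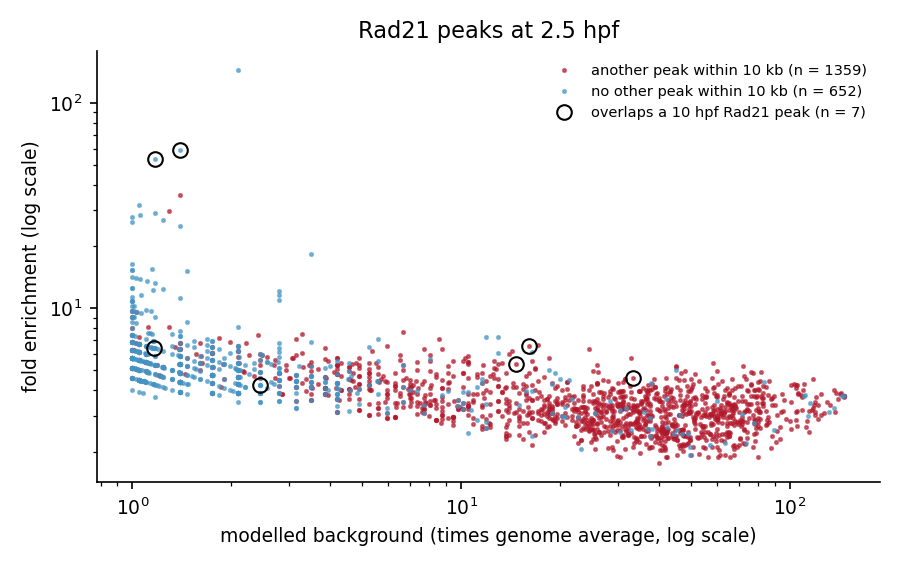
Fold enrichment (vertical axis, log scale) against the background modelled from input (horizontal axis, times the genome average, log scale) for the 2011 Rad21 peaks of 2.5 hpf, 1 point per peak. Red points are the 1359 peaks with another within 10 kb, blue points the 652 others, and circles the 7 peaks that overlap a 10 hpf Rad21 peak. Most red points lie at high background and low enrichment. The background was recovered from the fold enrichment, so the axes are not independent.

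Rad21 and CTCF shared many sites at 10 hpf. Of the 18075 Rad21 peaks, 3391 overlapped a CTCF peak, or 18.8% (18.2 to 19.3), where shifted peaks gave a mean of 66.7, a 50.8-fold excess (permutation p = 1e-04, the smallest the shifts can give, adjusted p = 2e-04). The same sites were 24.1% (23.4 to 24.8) of the CTCF peaks. Centres of overlapping peaks lay a median of 28 bp apart (quartiles 13 and 51). In the CTCF list the share at Rad21 fell from 68.5% (66.0 to 71.0) in the first decile to 4.48% (3.46 to 5.69) in the last, while in the Rad21 list the share at CTCF went from 25.4% (23.4 to 27.5) to 7.69% (6.51 to 9.02). The first 4 CTCF peaks all lay between 55775432 and 55790372 on chromosome 20 and overlapped Rad21 peaks of both 2.5 and 10 hpf. The next 3, at chromosome 8, 17070044 to 17070208, chromosome 4, 11111684 to 11111848, and chromosome 4, 10861118 to 10861282, overlapped no Rad21 peak.

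The share of Rad21 peaks at CTCF sites differed between stages. It was 0.15% (0.031 to 0.44) at 2.5 hpf, 11.9% (11.2 to 12.7) at 4.5 hpf and 18.8% (18.2 to 19.3) at 10 hpf. The increase from 4.5 to 10 hpf was 6.82 percentage points (bootstrap 95% interval 6.05 to 7.60, Fisher's exact test adjusted p = 6.2e-41). From 2.5 hpf the differences were 11.8 points to 4.5 hpf (10.97 to 12.6, Fisher's exact test adjusted p = 3.25e-91) and 18.6 points to 10 hpf (17.97 to 19.3, Fisher's exact test adjusted p = 3.94e-164). The 2.5 hpf list also differs in peak caller, peak width and library preparation, so neither of these differences can be ascribed to stage. At 4.5 hpf the 853 overlaps were 34.3 times the mean of shifted peaks (permutation p = 1e-04, the smallest the shifts can give), and the 3 at 2.5 hpf were 0.27 times (permutation p = 1). Seen from CTCF, 0.028% (0.0077 to 0.073) of its peaks lay at 2.5 hpf Rad21 peaks, 6.06% (5.67 to 6.47) at those of 4.5 hpf and 24.1% at those of 10 hpf. CTCF itself was measured at 10 hpf only, so the earlier Rad21 lists are compared with later CTCF sites.

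Rad21 peaks of 4.5 hpf that overlapped a 10 hpf Rad21 peak lay at CTCF sites more often than the others. Part of this is given by the overlap of Rad21 and CTCF at 10 hpf itself, since 10 hpf Rad21 peaks without a 4.5 hpf counterpart also lay at CTCF peaks in 17.5% of cases. Of the 2946 peaks of 4.5 hpf found again at 10 hpf, 25.02% (23.5 to 26.6) lay at a CTCF peak, against 2.76% (2.29 to 3.31) of the 4198 others (odds ratio 11.7, bootstrap 95% interval 9.59 to 14.7, Fisher's exact test adjusted p = 3.1e-186). The odds ratio was 11.3 (8.92 to 14.6) within deciles of the list. In the 10 hpf list 25.2% (23.6 to 26.8) of the peaks already present at 4.5 hpf and 17.5% (16.9 to 18.1) of the others lay at CTCF peaks (odds ratio 1.59, 1.44 to 1.74, Fisher's exact test adjusted p = 2.76e-21). Within deciles of the 10 hpf list that odds ratio was 1.098 (0.99 to 1.21), with a higher share among persisting peaks in 8 of 10 deciles, but in the first decile the direction was the opposite, with 21.3% of 1016 persisting peaks and 30.8% of 792 others at CTCF peaks. By class, 742 of the 10 hpf peaks lay at both 4.5 hpf Rad21 and CTCF, 2204 at 4.5 hpf Rad21 only, 2649 at CTCF only and 12480 at neither. The highest of the 742 were at chromosome 18, 49770556 to 49770744 (place 34), chromosome 19, 15234642 to 15234830 (place 69), and chromosome 5, 34156758 to 34156946 (place 71). No 10 hpf Rad21 peak overlapped both earlier Rad21 lists and CTCF.

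Chromosome 4, whose long arm is rich in repeats in zebrafish, held a large share of the 2.5 hpf peaks and a small one of all later peaks. It carried 318 of the 2011 peaks at 2.5 hpf, or 15.8% (14.2 to 17.5), which is 3.45 times (bootstrap 95% interval 2.31 to 4.78) its share of the chromosome length. The ratios were 0.78 (0.62 to 0.94) at 4.5 hpf, 0.70 (0.55 to 0.85) at 10 hpf and 0.67 (0.52 to 0.82) for CTCF. Of the 318 peaks, 315 lay beyond 24 Mb, against 84 of 255 at 4.5 hpf and 140 of 576 at 10 hpf. The odds of a peak on chromosome 4 were 5.07 times those of 4.5 hpf and 5.71 times those of 10 hpf (Fisher's exact test adjusted p = 8.97e-72 and 2.71e-98). Chromosomes 8 and 24 also stood above their length at 2.5 hpf, at 2.39 and 1.95 times, with bootstrap intervals that included 1. By Fisher's exact test, which takes neighbouring peaks as independent, 14 chromosomes differed between 2.5 and 4.5 hpf and 15 between 2.5 and 10 hpf. When 1 Mb windows were resampled instead, the 95% interval of the difference excluded 0 for 9 of the 14 and 7 of the 15, among them chromosome 4, whose share was 12.2 percentage points higher than at 4.5 hpf (6.32 to 19.01), but neither chromosome 8 nor 24. Between 4.5 and 10 hpf Fisher's exact test found 1 chromosome and the resampled windows 3, both including chromosome 3, which held relatively more peaks at 4.5 hpf (odds ratio 1.17, Fisher's exact test adjusted p = 0.044). The intervals from resampled windows, unlike Fisher's exact tests, were not adjusted for the number of comparisons, so the counts by the different methods are not directly comparable. With only the 478 peaks of 2.5 hpf on a background under 2 times the average, 1 chromosome differed from each later list, and chromosome 4 stood at 2.47 times its length share.

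**Figure D3:**
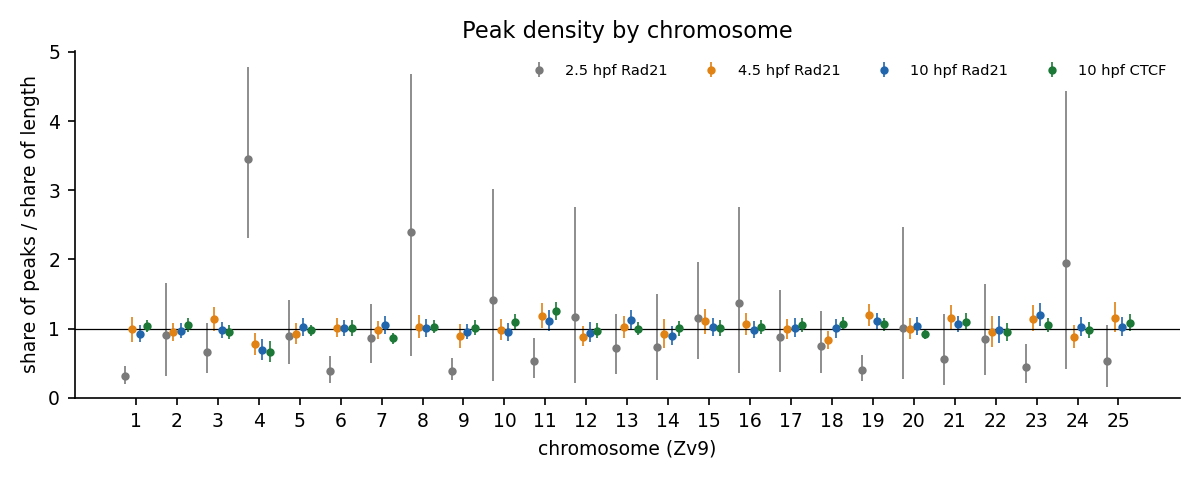
Share of a list's peaks on each Zv9 chromosome divided by that chromosome's share of length (vertical axis, points, with bootstrap 95% intervals over 1 Mb windows) for the 4 lists. The 2.5 hpf Rad21 list stands at 3.45 on chromosome 4, where the later lists stand between 0.67 and 0.78.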

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

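Tests on the 2.5 hpf list, on the number of tags and on peaks found again within the first decile were chosen after the overlaps had been seen, while those on the first 1000 peaks, on the first decile of 4.5 hpf at 10 hpf and on all 4.5 hpf peaks absent at 10 hpf were written down before their results.

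Differences between stages drew attention first. The share of Rad21 peaks at CTCF sites was higher at 10 than at 4.5 hpf by 6.82 percentage points, higher at 10 than at 2.5 hpf by 18.6 and higher at 4.5 than at 2.5 hpf by 11.8. The odds of a peak on chromosome 4 at 2.5 hpf were 5.07 times those at 4.5 hpf and 5.71 times those at 10 hpf. A peak outside the chromosomes was also flagged: the 2.5 hpf list holds one over the whole mitochondrial sequence, 1 to 16570, at a listed 3.76-fold enrichment, and no other list holds a mitochondrial peak. Its pileup of 418 tags is the ceiling with 1 tag kept per position, 2 times the fragment length of 209 bp, and 4 chromosomal peaks reached it too. Its background of 110.6 tags is the same ceiling for the inputs, scaled by the 5245276 over the 19827134 tags left. The mitochondrial fold is thus set by these tag totals and does not measure enrichment.

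Few Rad21 peaks of 2.5 hpf lay at Rad21 peaks of later stages. Of the 908 peaks with at least 4-fold enrichment 7, or 0.77% (exact 95% interval 0.31 to 1.58), overlapped a 10 hpf peak. The share was higher among the 38 peaks of at least 10-fold enrichment, at 2 peaks or 5.26% (0.64 to 17.7). Of the 478 peaks on a background under 2 times the average 3, or 0.63% (0.13 to 1.82), overlapped a 10 hpf peak. Neither cut thus left a list that was largely shared. With 7 shared peaks among 2011, no subset of 908 or 478 could have reached a high share. These outcomes followed from the counts and are no separate tests of a looser threshold or of high-copy sequence hiding shared peaks. Sequence with more copies than the assembly shows may account for part of the dense runs, with a median background of 28.3 times the average. Among the 478 peaks alone the share with another of them within 10 kb was 12.6%, against 67.6% for all peaks. That was still 15.3 times the share of uniform positions, which argues against extra copies as the whole cause. Shallow and redundant libraries stay open and cannot be told apart from absent binding. A mean 4.5 hpf peak of 20.5 tags would have 7.54 tags at the depth of 2.5 hpf. Scaled by the tags left after the limit per position, it would have 9.12. The smallest listed pileup was 6 and the median 40, or 10 for peaks on a background under 2 times the average. Tags in a peak and coverage at a summit are unlike measures, and enrichment at 2.5 hpf at the later sites was not measured. The peak caller, the library kit and the biological stage also differ together at 2.5 hpf and were not separated.

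Rad21 peaks were more numerous at 10 than at 4.5 hpf. More sequenced tags are argued against, since the 10 hpf libraries had 0.93 times the total tags of 4.5 hpf and 1.001 times those left after the limit per position. Filtering against each stage's own input removed 11034 of 18663 putative peaks at 4.5 hpf and 16425 of 35851 at 10 hpf. Putative peaks were thus already more numerous at 10 hpf before this filter. How much the filter adds to the difference was not tested. Better enrichment of the same sites at 10 hpf is a candidate explanation for part of the difference, since 92.6% of the first decile of the 4.5 hpf list overlapped a 10 hpf peak, but new sites gained beside the earlier ones would give the same value. It leaves the 4198 peaks of 4.5 hpf without a counterpart at 10 hpf unaccounted for. A gain of binding sites with stage remains open and was not tested.

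For the larger share of Rad21 peaks at CTCF sites at 10 than at 4.5 hpf, weak calls that dilute the 4.5 hpf list stay open. Among the first 1000 peaks of each Rad21 list, set against the full CTCF list, the difference was 8.20 points (bootstrap 95% interval 5.32 to 11.02). The shares were 21.9% at 10 hpf and 13.7% at 4.5 hpf. With the first 1000 CTCF peaks as well the difference was 6.3 points (4.15 to 8.53), with 12.5% and 6.2%. This cannot decide on dilution, because most of these 4.5 hpf peaks are of the first decile, whose share of 11.05% was below that of the second. At 4.5 hpf the share was 21.8% in the second decile, 20.1% in the third and 5.18% in the last. At 10 hpf it was 28.2%, 25.5% and 7.69% in the same deciles, higher in each. Peaks of 4.5 hpf that are absent at 10 hpf may account for part of the larger share at 10 hpf. Of them, 2.76% lay at CTCF peaks, against 25.02% of those found again. At the top of the lists such absent peaks are argued against by their number alone, since 662 of the 715 peaks in the first decile of 4.5 hpf were found again. Of these, 11.8% (exact 95% interval 9.43 to 14.5) lay at CTCF peaks, against 20.1% (17.3 to 23.3) of the first 715 peaks of 10 hpf. This outcome followed from the counts and is no separate test. It covers only the first decile of 4.5 hpf, whose share at CTCF was below that of the second. Whether those absent peaks were lost binding sites or false calls was not tested, and CTCF was measured at the later stage only, so a site that changed between the stages in both proteins would look the same.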

How the results depend on the processing

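No paired analysis was possible because a single list was deposited per stage and antibody, and for the same reason no library could be left out. Alternatives by place in the list, by 2.5 hpf enrichment or background, by leaving out the end of chromosome 20 and by resampled windows for chromosomes were chosen after seeing the data; the others were planned, and planned ones that need a score in every list, genes or sequence were not run. Of 140 alternative values, 111 kept their direction and side of the threshold or stayed within their limits. The overlap of 4.5 with 10 hpf Rad21 stayed between 32.1 and 808 times the shifts over 9 alternatives, that of Rad21 with CTCF between 18.6 and 319, and the difference at CTCF between 10 and 4.5 hpf between 5.92 and 8.35 points over 8. The overlap of 2.5 hpf peaks turned from below to above the shifts, without passing the test, with the first 2011 peaks of each list (1.22 times for 4.5 hpf, 2.40 times for 10 hpf) and with peaks of at least 4-fold enrichment (1.12 times for 10 hpf); the cause was not tested. CTCF peaks went to 0.91 times the uniform positions within 5 kb, where the minimum distance between HOMER peaks lowers the number, and to 1.05 times, past the test, within 50 kb. The share of CTCF peaks at Rad21 was 0.0071%, 5.34% and 22.5% for 2.5, 4.5 and 10 hpf when 50% of the shorter peak had to overlap, 24.9% for 10 hpf with centres within 500 bp, and 0.20%, 11.04% and 17.0% with the first 2011 peaks. The top 50% of the 2.5 hpf list by q held 1006 peaks by construction. Chromosomes that differed from the 2.5 hpf list numbered 8, 7 and 7 (4.5 hpf, 10 hpf, CTCF) with 4-fold peaks and 1 each with low-background peaks, of which there are fewer, and 9, 7 and 7 with resampled windows, which gave 3 between 4.5 and 10 hpf Rad21; with the first 50% of each list, 2 differed between 4.5 and 10 hpf Rad21 and 5 between 10 hpf Rad21 and CTCF. Density on chromosome 4 was 2.91, 5.08 and 2.47 at 2.5 hpf with the first 50%, 4-fold and low-background peaks, and 0.77 for the first 50% of CTCF; the cause was not tested. The 2.5 hpf list rests on 5245276 tags after duplicates were removed, fewer than each of the others.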

Other observations

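The comparisons in this part were all chosen after the data were seen.

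Rad21 peaks in the first decile of the 4.5 hpf list lay at CTCF sites less often than those of the second decile. In the first decile 11.05% (exact 95% interval 8.85 to 13.6) overlapped a 10 hpf CTCF peak and in the second decile 21.8% (18.8 to 25.03), a difference of -10.8 percentage points (bootstrap 95% interval -14.7 to -6.89, Fisher's exact test adjusted p = 9.35e-08 over both Rad21 lists). Later deciles were not all above the first: the fifth stood at 10.6% and the last at 5.18%. At 10 hpf the same comparison gave 25.4% and 28.2% and did not pass (Fisher's exact test adjusted p = 0.071). In the first decile of the 10 hpf list, peaks already present at 4.5 hpf lay at CTCF less often than the others, 21.3% against 30.8%, a difference of -9.55 points (bootstrap 95% interval -13.6 to -5.49, Fisher's exact test adjusted p = 4.65e-05 over the 10 deciles). Peaks already present at 4.5 hpf lay at CTCF more often than the others in 8 of the 10 deciles, with differences up to 10.4 points in the fourth (Fisher's exact test adjusted p = 0.000867). Of these 8 only the fourth passed, the next lowest being the sixth (Fisher's exact test adjusted p = 0.057). None of the first 10 Rad21 peaks at 4.5 or at 10 hpf overlapped a CTCF peak, among them chromosome 8, 451866 to 452054, chromosome 2, 55796815 to 55797003, and chromosome 3, 17297510 to 17297698.

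CTCF and Rad21 differed in where along the chromosomes they lay. Of the CTCF peaks 40.3% (bootstrap 95% interval 37.3 to 43.1) lay within 10 Mb of a chromosome end, which is 36.9% of the length, against 32.0% (29.4 to 34.8) of the Rad21 peaks of 10 hpf. The difference of 8.24 percentage points (6.95 to 9.46, Fisher's exact test p = 1.07e-52) had the same sign on 25 of 25 chromosomes. Rad21 peaks of 10 hpf at CTCF sites lay there in 37.1% of cases and the other Rad21 peaks in 30.9%. The share was 35.7% (32.7 to 38.7) in the first 50% of the CTCF list and 44.9% (41.8 to 47.9) in the remainder. Within 10 Mb lay 36.2% (33.2 to 39.2) of the 4.5 hpf Rad21 peaks, between CTCF and 10 hpf Rad21. The order was the same within 5 Mb, with 19.9% at 4.5 hpf, 16.2% for 10 hpf Rad21 and 20.9% for CTCF. Within 1 Mb the shares were 6.52% (4.87 to 8.28), 4.54% (3.41 to 5.77) and 5.20% (3.87 to 6.57) in the same order of lists. These intervals overlap, and the shares within 1 Mb were not tested. In 1 Mb windows, CTCF gained most over Rad21 at chromosome 2 from 59 Mb, with 28 CTCF and 9 Rad21 peaks, and Rad21 most over CTCF at chromosome 13 from 30 Mb, with 41 Rad21 and 9 CTCF peaks, and chromosome 1 from 46 Mb, with 33 and 5.

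Overlaps of 2.5 hpf Rad21 peaks with later peaks were few even against the shifts, but this did not hold in all subsets. The lower tail of shifts along whole chromosomes gave permutation p = 0.076 for 4.5 hpf Rad21, 0.022 for 10 hpf Rad21 and 0.0042 for CTCF, 3 tests without adjustment, of which the one for 4.5 hpf did not pass. Against the mean of the shifts the overlaps with 10 hpf Rad21 stood at 0.46 times for all peaks, 0.997 times for those on a background under 2 times the average, 1.12 times for those of at least 4-fold enrichment and 2.40 times for the first 2011 peaks of each list, but at 0.278 times without the end of chromosome 20; those with 4.5 hpf Rad21 stood at 0.35, 0.87, 0.85 and 1.22 times. Against shifts of 10 to 100 kb the overlaps of all peaks stood at 0.75 times for 10 hpf and 0.52 times for 4.5 hpf. A small part of the 2.5 hpf list stood apart by its enrichment: 38 peaks had at least 10-fold enrichment, and none of them lay on chromosome 4. Their median background was 1.08 times the average, which is in part given by the selection, since background was recovered from fold. Of the 38 peaks, 2 overlapped a 10 hpf Rad21 peak and none overlapped a CTCF peak. The end of chromosome 20 is the one place where the first CTCF peaks, 10 hpf Rad21 peaks and 2.5 hpf Rad21 peaks coincide, and the 3 peaks of 2.5 hpf there had a background of 14.7, 33.2 and 16.1 times the average.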
